A study of Homo sapiens with 52 samples.

How the data were processed

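RNA of sorted CD4+ Treg and Tcon taken on day 14 after transplant was sequenced from 52 libraries. Per the labels, total RNA was extracted with a Zymo Quick-RNA Microprep kit and libraries were made with the KAPA HyperPlus kit. Per the submitters' processing notes, reads were aligned with STAR 2.6.1 to GRCh38 and quantified with RSEM, whose version, like the annotation release and the strandedness, is not given in the sources used here. The deposited table holds expected counts of RSEM for 67071 genes in 52 columns, not normalized, of which 17.1% are fractional. Each column was matched to its label by the library name, with 0 columns unmatched, and expected counts were rounded to whole numbers for the count models. Replicate numbers of a group follow the order of the samples in the series and pair nothing.

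Genes were named by the Ensembl identifier and symbol in the table, and coordinates came from GENCODE 29, which matched 87.2% of the genes. Genes of the Y chromosome, the Y copies of pseudoautosomal genes and the X-inactivation transcripts (570 in all) were left out of every test. The X copies of pseudoautosomal genes were kept. 1952 symbols stood on more than 1 line of the table, mostly copies on alternative haplotypes, which were tested as separate genes. Fits were made with edgeR 4.0.16 in R 4.3.3: filterByExpr (minimum count 10, minimum total 15), TMM scaling, robust quasi-likelihood dispersion and F-tests, and Benjamini-Hochberg adjustment with a threshold of 0.05. The library series in the library names (the Pool series and 2 numbered series) entered every model as a covariate. Arm comparisons within Treg used all 27 Treg libraries (22962 genes, 22 residual degrees of freedom, common dispersion 0.773), those within Tcon all 25 Tcon libraries (21205 genes, 20 degrees of freedom, dispersion 0.654), and Treg against Tcon and the 2 differences of arm effects all 52 (27493 genes, 44 degrees of freedom, dispersion 0.870), for 9 comparisons in all.

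Depth per library is the sum of its expected counts. The medians in M (1000000 counts) were 25.8, 20.3 and 8.75 for no-prophylaxis, prophylaxis and SOC Treg, and 24.3, 26.8 and 23.9 for the Tcon groups. Log2 CPM used TMM scaling and a prior count of 2. Means, SD, list scores and permutation tests left out the 4 libraries under 1000000 counts, since their values per gene rest on few reads. Pairs of these 48 libraries within a group were checked for duplicates, and none of 183 pairs was one (smallest chi-square per gene 45.6).

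The 32 gene lists were chosen before the data were examined: Treg identity, conventional CD4, NFAT targets, Th1 and cytotoxic, Th2, Th17, Tfh, naive and central memory, proliferation, activation, inhibitory receptors, type I interferon, interferon gamma, IL-2 and STAT5, tissue homing, immediate early, NF-kB, glucocorticoid, p53, glycolysis, oxidative phosphorylation, cholesterol, ribosomal proteins, mitochondrially encoded genes, histones, and markers of monocytes, neutrophils, B cells, NK cells, CD8 and γδ T cells, erythroid cells and platelets. Each was tested with camera of limma 3.58.1 at a preset correlation of 0.01, with an estimated correlation, and with fry, adjusted over the 32 lists. For each list the members past the threshold were counted when adjusted over all genes and when adjusted over the list alone. A list score is the mean log2 CPM of all its members in a library, those too low to be tested included. Fitted medians rest on the tested members alone, so a score and a median can rest on different genes. Scores were compared by exact permutation of the arm labels, or by 100000 random regroupings for Treg against Tcon, 2-sided and without regard to series, with adjustment over the lists. Libraries beyond the median count those of the first group past the median of the second in the direction of the fold change.

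Named genes follow a rule set with the lists. In each comparison these were up to 8 genes with the largest and up to 8 with the most negative fold change among those past the threshold with a mean of at least 1 log2 CPM, and up to 3 members of each list past the threshold. FOXP3, IL2RA, CTLA4, IKZF2, IL7R, CD40LG, MKI67, IL2 and IFNG were always named. Where fewer than 10 genes passed, list members past the threshold over the list alone were added, and for the differences of arm effects the 5 genes with the smallest p. Polymorphic HLA and KIR genes, receptor segments, pseudogenes and unnamed clones were never named. LYZ and HBB are given as markers of other cells.

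The alternatives were DESeq2 1.42.0 (independent filtering at 0.05), RLE scaling, no low-count filter, a minimum count of 50, no series covariate, the Pool series alone, the 2 numbered series alone, no libraries under 1000000 counts, voom with quality weights, 2 surrogate variables from sva 3.50.0, all 52 libraries in one fit, and leaving out each library. After the data were seen, further fits left out 2 libraries chosen by FOXP3. These were labelled prophylaxis Treg (the lowest of its group) and SOC Tcon (the highest of its group). Other such fits left out the 15 libraries with over 35000 genes, summed the lines of one symbol, or added the monocyte and erythroid scores as covariates. Still others repeated DESeq2 without the small libraries, or took pairs of library numbers as a block. Up to 100 splits of the libraries into groups of the same sizes within each cell type, or 40 for fits of all libraries, were fitted the same way. The fits were tested on simulated data with 50 genes at each of 4 planted sizes: at a log2 fold change of 1, 2, 3 and 4, SOC against no prophylaxis recovered 10%, 66%, 90% and 92% in Tcon, and 4%, 46%, 68% and 94% in Treg.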

Results

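Day 14 after transplant, sorted CD4+ regulatory T cells (Treg) and conventional T cells (Tcon) were compared between 3 arms. Per the labels, patients received Orca-T with no prophylaxis against graft-versus-host disease (the no-prophylaxis arm), Orca-T with a single agent, tacrolimus per the title of the series (the prophylaxis arm), or standard of care (SOC). Orca-T is a donor graft whose stem cells, Treg and Tcon are given as separate fractions, and tacrolimus blocks calcineurin and through it NFAT. The contents of standard of care are not given in the sources used here. The 52 libraries formed 6 groups: Treg with 11 no-prophylaxis, 9 prophylaxis and 7 SOC libraries, and Tcon with 10, 8 and 7. The titles of the Tcon samples name the cells CD4. The labels carry no patient identifiers, so Treg and Tcon were compared as unpaired groups. Every p of a single gene or of a list score measures the spread between libraries. The p of a list by camera sets its members against all other genes, with a preset or an estimated correlation between genes.

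FOXP3, the transcription factor of Treg, averaged 8.16 ± 1.66 log2 CPM (counts per 1000000, mean ± SD) in 23 Treg libraries and 6.94 ± 1.61 in 25 Tcon libraries. Depth was uneven: 48 libraries held 2.03 to 95.5 M counts (M, 1000000), and the 4 others held 21, 2184 and 3888 counts and 0.782 M. The 3 smallest were all SOC Treg, which left 4 SOC Treg libraries of usable depth, and the last was prophylaxis Treg, which left 8. All 52 libraries stayed in the fits, as planned, and means, scores and permutation tests used the 48. 1 library labelled Treg had a FOXP3 level of 2.80, the lowest of the Treg, and 1 library labelled SOC Tcon had a FOXP3 of 8.73 (others of its group 3.31 to 6.14) and a Treg identity score without FOXP3 of 6.25, where other Treg had a median of 5.96. FOXP3 alone did not set that library apart from all Tcon, since no-prophylaxis Tcon reached 9.09.

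**Figure D1:**
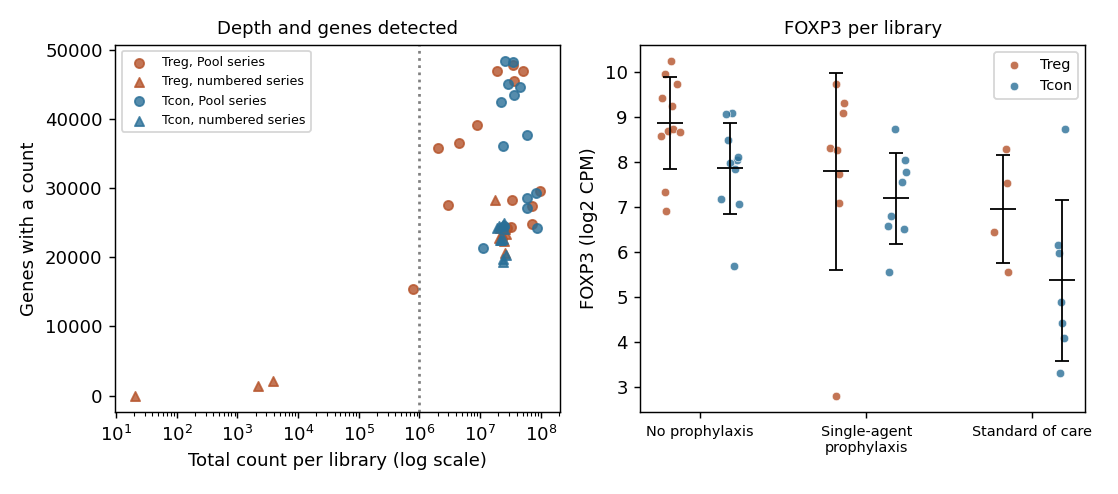
Left, total count per library (log axis) against genes with a count, with circles for the Pool series and triangles for the 2 numbered series; the dotted line marks 1000000 counts, and 15 Pool libraries exceed 35000 genes. Right, FOXP3 log2 CPM per library (points) by arm and cell type with bars at mean ± SD; the lowest Treg point lies at 2.80.

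Whether the sorted cells carried the transcripts of their labels was the question of the comparison of Treg with Tcon over all arms. Genes of Treg identity were higher in Treg: all 21 members of the list had a higher fitted level, with a median log2 fold change of 0.82, and 13 passed when adjusted over the list alone (0 over all genes). The list rose by camera (adjusted p = 0.00762 with an estimated correlation). Its score was 5.95 ± 0.92 in Treg and 5.12 ± 0.88 in Tcon (difference 0.83, permutation p = 0.00279, adjusted p = 0.0434, 19 of 23 Treg libraries over the Tcon median). The cytotoxic and Th1 genes were lower in Treg by a median of −1.03, with 9 of 22 members lower and 0 higher over the list alone (adjusted p = 0.0212 with an estimated correlation). Their score differed by −0.81 (permutation p = 0.00407, adjusted p = 0.0434, 20 of 23 libraries).

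IL2RA, the high-affinity IL-2 receptor chain, had a log2 fold change of 1.27 ± 0.29 (SE; adjusted p = 0.205 over all genes, 21 of 23 libraries), and FOXP3 1.18 ± 0.33 (adjusted p = 0.388, 18 of 23). Other members of the list past the threshold over the list alone were TNFRSF9 (1.41 ± 0.36), LRRC32 (1.16), CCR8 (1.06), LAYN (1.23), HPGD (0.99) and IKZF2 (1.13 ± 0.36, 20 of 23 libraries). GZMB, a granzyme of cytotoxic cells, had a fold change of −2.48 ± 0.57 (3.36 ± 1.71 against 5.51 ± 2.39, 21 of 23), GZMK −1.83 ± 0.42 (22 of 23), GZMH −2.24, FGFBP2 −1.93 ± 0.44 and EOMES −1.45. The CD8 and γδ T cell list had a median of −0.94 (adjusted p = 0.0672 with an estimated correlation; score difference −0.75, permutation p = 0.00374, adjusted p = 0.0434). Erythroid transcripts had a median of −2.67, with 12 of 12 members lower over the list alone, but adjusted p = 0.128 with an estimated correlation and permutation p = 0.146 for the score. MKI67 (0.23), IL7R (−0.08), CTLA4 (0.58), CD40LG (−0.63), IL2 (−0.59) and IFNG (−1.17) did not pass over all genes, and the proliferation list had a median of −0.06.

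No gene passed over all 27493 in the unpaired edgeR fit, where 1092 had an unadjusted p under 0.05; DESeq2 called 10811 and voom 7, and DESeq2 without the 4 small libraries called 60. A further fit left out the library labelled prophylaxis Treg with the lowest FOXP3 of its group and the library labelled SOC Tcon with the highest. With edgeR 29 genes were called without these 2 libraries, and 12 when the small libraries were left out too. Those 2 were chosen after the data were seen and by a Treg marker, which itself bears on the count. Of the 32 lists, 21 passed with the preset correlation (2 higher, 19 lower) and 2 with an estimated one. With fry 0 passed. The score difference of Treg identity was 0.93 within the Pool series and 0.02 and 1.16 within the 2 numbered series, and the list did not pass in these 2 alone (adjusted p = 0.546 with an estimated correlation). The 0.02 came from 3 Treg and 4 Tcon libraries that include the 2 just named. It was 1.24 without the one labelled Treg and 1.41 without both, again with libraries chosen by a member of the list. The Th1 and cytotoxic list did not pass there either (0.281), nor with monocyte and erythroid covariates (0.0606).

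Tcon of SOC were set against Tcon of Orca-T without prophylaxis to ask how the 2 regimens differ in conventional T cells. Single cell-cycle genes fell in Tcon of the SOC arm (n = 7) against the no-prophylaxis arm (n = 10), while the proliferation list passed with the preset correlation alone (adjusted p = 0.0963 with an estimated correlation). MKI67, a marker of dividing cells, fell by a log2 fold change of −3.56 ± 0.75 (SE; adjusted p = 0.0401; 3.11 ± 0.89 against 6.14 ± 1.98 log2 CPM). The inhibitory receptor HAVCR2 (TIM-3) fell by −2.38 ± 0.45 (adjusted p = 0.0326; 3.06 ± 0.64 against 5.21 ± 1.12) and FOXP3 by −2.26 ± 0.54 (adjusted p = 0.0442; 5.36 ± 1.79 against 7.85 ± 1.02). TCF7, a transcription factor of naive and memory T cells, rose by 1.34 ± 0.31 (adjusted p = 0.0405; 9.15 ± 0.97 against 7.94 ± 0.69). AK5, an adenylate kinase, rose by 3.10 ± 0.68 (adjusted p = 0.0401; 4.98 ± 1.03 against 1.44 ± 2.20). All 7 SOC libraries lay beyond the no-prophylaxis median for MKI67, HAVCR2 and AK5, and 6 of 7 for FOXP3 and TCF7. In all, 226 of 21205 genes passed with edgeR, 78 higher and 148 lower in SOC. This balance did not hold in every fit. Without the library labelled SOC Tcon with the highest FOXP3 of its group, 43 were higher and 28 lower. With 2 surrogate variables these were 141 and 138, and without SOC library 6 or 7 the calls were 23 and 11 or 15 and 8.

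All 30 members of the proliferation list were lower when adjusted over the list alone, and 14 over all genes, with a median of −3.02. The camera call of the list was lost with an estimated correlation (adjusted p = 0.0963). Among them TK1 (−3.78 ± 0.81), which makes nucleotides for DNA synthesis, and TPX2 (−3.12 ± 0.68), a spindle protein, fell and lay below the no-prophylaxis median in all 7 SOC libraries. Also lower were the cell-cycle genes DEPDC1 (−4.22), CCNA2 (−4.04), UBE2C (−4.52), PLK1 (−4.24), TRIP13 (−4.89) and the histone gene H2AC12 (−4.29), whose reads near-identical histone copies can share. The list score was 3.24 ± 0.74 in SOC and 5.76 ± 1.73 in no prophylaxis, a difference of −2.53 (exact permutation p = 0.0036, adjusted p = 0.0288), and −2.34, −3.62 and −2.24 within the 3 series. In the same libraries the monocyte and dendritic cell score was 2.50 ± 2.92 in SOC against 5.44 ± 1.96, and LYZ, a monocyte transcript, 6.06 ± 2.48 against 8.43 ± 2.44.

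Inhibitory receptors, activation genes and Treg identity genes fell together, and these 3 lists passed with an estimated correlation; CTLA4, TIGIT and ENTPD1 belong to more than 1 of them. The inhibitory receptors had a median of −1.09 (6 of 12 lower over the list alone, 1 over all genes, adjusted p = 0.0174 with an estimated correlation). Their score fell by −1.05 (3.66 ± 0.39 against 4.71 ± 0.41, exact permutation p = 0.000206, adjusted p = 0.00659). The activation list had a median of −0.93 (8 of 16 lower over the list alone, 2 over all genes, adjusted p = 0.0328 with an estimated correlation) and a score lower by −1.10 (exact permutation p = 0.00072, adjusted p = 0.0115). It includes TNFRSF1B, the second TNF receptor, which fell by −1.64 ± 0.34. Treg identity genes had a median of −1.20 (10 of 21 lower over the list alone, 2 over all genes, adjusted p = 0.0328 with an estimated correlation). Their score fell by −1.26 (exact permutation p = 0.00735, adjusted p = 0.0392), and by −1.32, −1.47 and −1.34 within the 3 series. In no-prophylaxis Tcon this score was 5.57 ± 0.66, above the 5.13 ± 0.58 of SOC Treg. The values cannot tell a change within Tcon from a different share of Treg in the libraries, which was not measured. Beside FOXP3, CTLA4 had −1.48 ± 0.40 (adjusted p = 0.0646), IKZF2 −1.63 ± 0.55 (0.129) and IL2RA −0.99 ± 0.51 (0.344), none past the threshold over all genes.

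**Figure D2:**
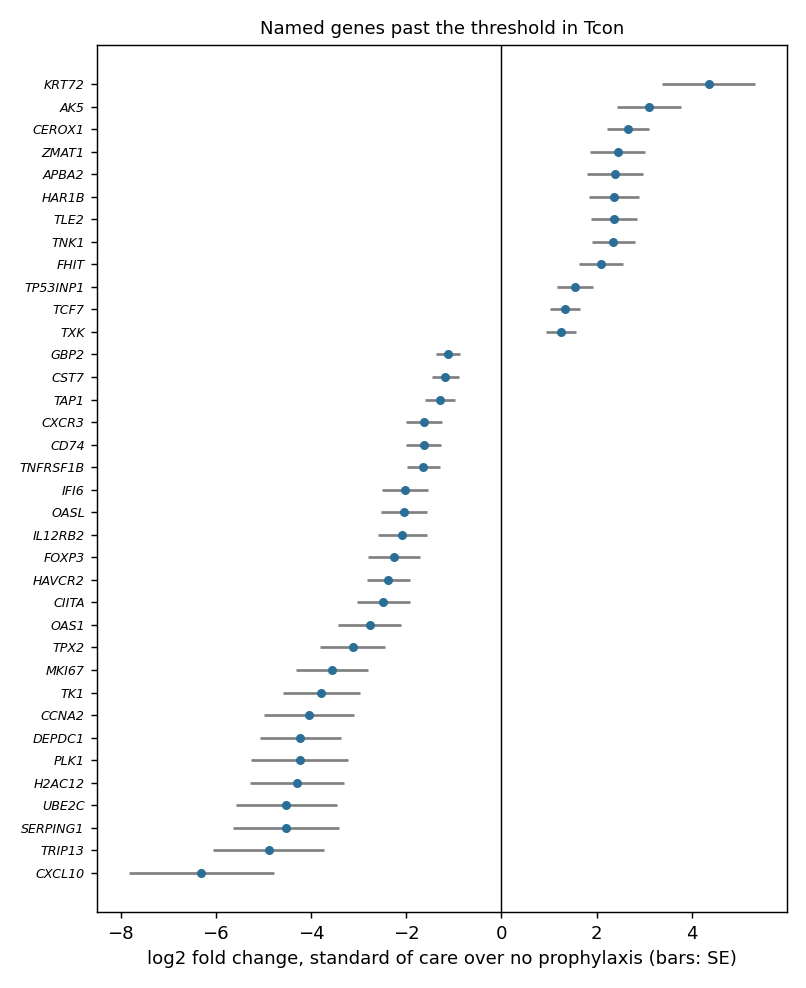
Log2 fold change (points) ± SE (bars) in Tcon of SOC against no prophylaxis for named genes past the threshold, one gene per line. CXCL10 was lowest at −6.30 and KRT72 highest at 4.35.

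Genes of naive and central memory T cells rose: 3 of 18 passed over all genes and 6 over the list alone, all higher, with a median of 0.69 (adjusted p = 0.0328 with an estimated correlation). Their score was 7.37 ± 0.63 against 6.53 ± 0.39 (difference 0.84, exact permutation p = 0.00519, adjusted p = 0.0332, 6 of 7 libraries). TXK, a T cell kinase, rose by 1.25 ± 0.31, FHIT by 2.09 ± 0.47, KRT72 by 4.35 (6 of 7), APBA2 by 2.39 (6 of 7), and the p53 target TP53INP1 by 1.54 ± 0.38 (5 of 7). CEROX1 (2.66 ± 0.45, adjusted p = 0.0248), HAR1B (2.36), TNK1 (2.35), TLE2 (2.36) and ZMAT1 (2.44) also rose. The strandedness of the libraries is not given in the sources used here, so for the noncoding CEROX1 and HAR1B the strand of the reads is open. IL7R had 0.98 ± 0.40 (adjusted p = 0.213), CD40LG 0.33 ± 0.39 and IL2 −0.36 ± 0.72, none past the threshold.

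Interferon-induced genes fell as single genes, and their lists lost the call with an estimated correlation. OASL (−2.04 ± 0.48), OAS1 (−2.77 ± 0.66) and IFI6 (−2.02 ± 0.48), antiviral genes induced by type I interferon, were among 4 of 33 list members lower over all genes and 11 over the list alone. That list had a median of −1.12 (adjusted p = 0.252 with an estimated correlation) and a score difference of −0.98 (exact permutation p = 0.0272, adjusted p = 0.0725). For interferon gamma, GBP2 (−1.12 ± 0.26), TAP1 (−1.29), which the table holds on 8 lines for haplotype copies, and CIITA (−2.48 ± 0.55), the regulator of MHC class II, were lower. CXCL10 (−6.30 ± 1.53), SERPING1 (−4.53) and CD74 (−1.63 ± 0.37) fell as well. The monocyte and dendritic cell score was also lower in these libraries (2.50 ± 2.92 in SOC against 5.44 ± 1.96). With it and the erythroid score as covariates 0 genes passed. A part of monocyte RNA in the falls of these genes, and of HAVCR2 and TNFRSF1B above, is thus open. The interferon gamma list had 4 of 24 members lower over all genes and 10 over the list alone (median −1.01, adjusted p = 0.0989 with an estimated correlation). Its score fell by −1.05 (exact permutation p = 0.00226, adjusted p = 0.0241). The Th1 genes CXCR3 (−1.63 ± 0.38), IL12RB2 (−2.08, 6 of 7) and the cystatin CST7 (−1.18 ± 0.28) fell, with 3 of 22 Th1 members lower over all genes and 6 over the list alone. The Th1 list had a median of −1.16 (adjusted p = 0.24 with an estimated correlation) and a score difference of −1.28 (exact permutation p = 0.0173, adjusted p = 0.0554). IFNG had −2.78 ± 1.21 (adjusted p = 0.25).

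**Figure D3:**
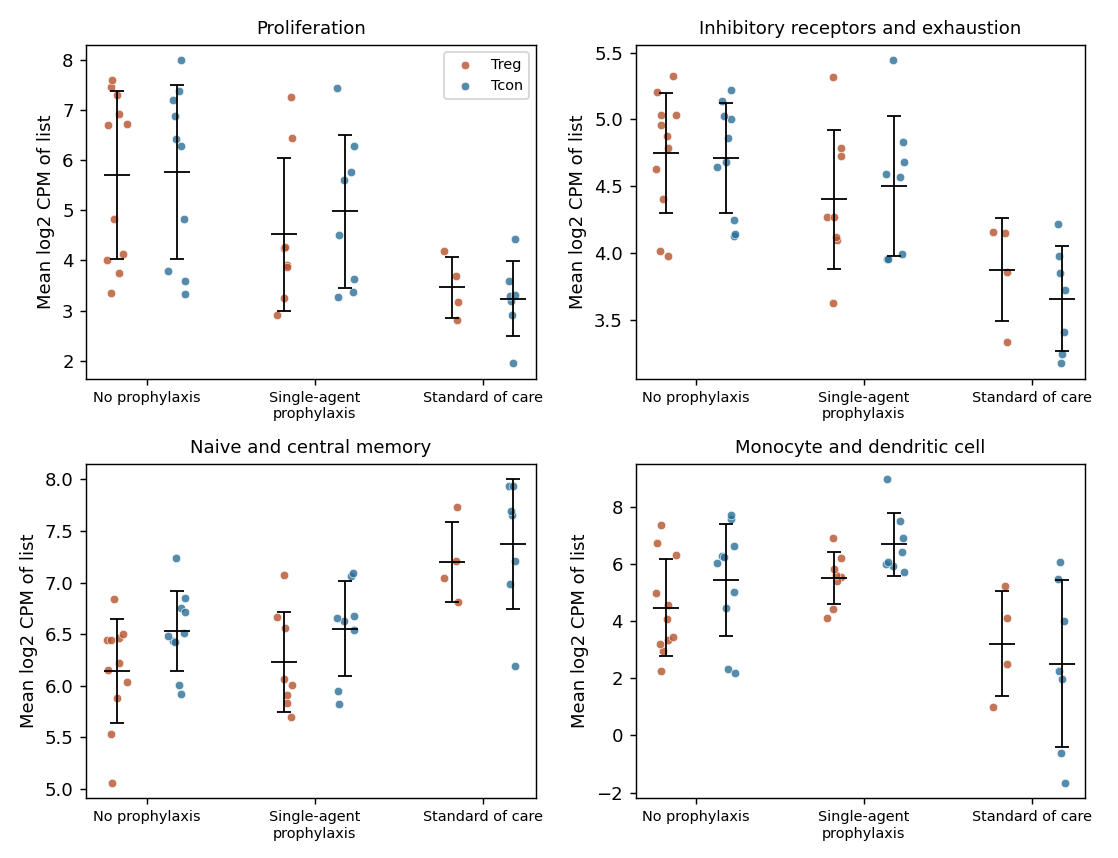
Mean log2 CPM of the members of 4 lists (proliferation, inhibitory receptors, naive and central memory, monocyte and dendritic cell) per library (points), by arm and cell type, with mean ± SD. In Tcon the proliferation score was 3.24 ± 0.74 in SOC and 5.76 ± 1.73 in no prophylaxis.

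Monocyte and dendritic cell genes had a median of −2.50 in this comparison, 12 of 17 lower over the list alone (adjusted p = 0.158 with an estimated correlation; score −2.94, exact permutation p = 0.0246, adjusted p = 0.0716, and −1.63, −5.43 and −1.99 within the 3 series). Further lists passed with the preset correlation alone. These were, by median and adjusted p with an estimated correlation, NFAT targets (−0.71, 0.158), tissue homing (−0.23, 0.13), glycolysis (−0.47, 0.352), oxidative phosphorylation (−0.31, 0.54), histones (−0.66, 0.268), neutrophil (−1.84, 0.484), erythroid (−1.07, 0.558) and platelet (−1.47, 0.37) genes. Higher were conventional CD4 (0.83, 0.252), p53 (0.38, 0.413) and ribosomal protein genes (0.65, 0.369, 26 of 26 members higher). Not past the threshold were Th2 (0.15), Th17 (0.07), Tfh (−0.67), IL-2 and STAT5 (−0.38), immediate early (−0.12), NF-kB (0.17), glucocorticoid (0.37), cholesterol (−0.20), mitochondrially encoded (0.25), B cell (−1.36), NK (1.01) and CD8 and γδ (−0.47) genes. For the NK and Th2 lists camera pointed down although the median was positive.

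DESeq2 called 1478 and voom 1303 genes here, no low-count filter left 7, and the Pool series alone and the 2 numbered series alone left 0, with MKI67 at −3.24 and −3.92. With the monocyte and erythroid scores as covariates, tried after the data were seen, 0 passed, with HAVCR2 at −1.59, MKI67 at −2.61 and AK5 at 3.11. With an estimated correlation, inhibitory receptors and Treg identity kept their call under the covariates (adjusted p = 0.02 each) and activation (0.114) and naive and central memory genes (0.0896) lost it, as did all 4 in the 2 numbered series alone. Of the 226 calls, 0 remained without no-prophylaxis library 1 or 10 or SOC library 1, 4 or 5. The count was 2, 125, 13, 53, 447, 4 and 651 without no-prophylaxis library 2, 3, 5, 6, 7, 8 and 9, and 71, 130, 34 and 23 without SOC library 2, 3, 6 and 7. MKI67 is ENSG00000148773.14 (chromosome 10, 128096659 to 128126385), HAVCR2 ENSG00000135077.9 (chromosome 5, 157085832 to 157142869), FOXP3 ENSG00000049768.16 (chromosome X, 49250436 to 49264826), TCF7 ENSG00000081059.20 (chromosome 5, 134114711 to 134151865) and AK5 ENSG00000154027.19 (chromosome 1, 77282051 to 77559969), all on GRCh38.

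The matching question in Treg, SOC against no prophylaxis, rested on 4 SOC libraries of usable depth and 11 no-prophylaxis libraries. AK5 rose by 3.24 ± 0.56 (adjusted p = 0.0411; 4.66 ± 0.57 against 0.98 ± 1.59 log2 CPM). NETO2, an accessory subunit of kainate receptors, fell by −2.47 ± 0.41 (adjusted p = 0.0411; 3.59 ± 0.34 against 6.07 ± 0.60). All 4 SOC libraries lay beyond the no-prophylaxis median for both, and these 2 of 22962 genes were the only ones past the threshold with edgeR (1833 had an unadjusted p under 0.05). NETO2 is ENSG00000171208.10 (chromosome 16, 47077703 to 47143997, GRCh38). Within the Pool series the folds were 2.96 for AK5 and −2.18 for NETO2, and within the 2 numbered series, with 1 SOC library of usable depth, 3.81 and −3.25.

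Lists of activation and inhibitory receptors fell in SOC Treg with an estimated correlation. The inhibitory receptors had a median of −1.30 (6 of 12 lower over the list alone, adjusted p = 0.0291 with an estimated correlation) and a score difference of −0.87 (exact permutation p = 0.00586, adjusted p = 0.0703). HAVCR2 had −2.14 ± 0.51, TIGIT −1.76 and LAG3 −2.65, each past the threshold over the list alone, and no member of any list passed over all genes. The activation list had a median of −1.11 (6 of 16 over the list alone, adjusted p = 0.0291 with an estimated correlation, and 0.0546 without the 4 small libraries). Its members CD58 (−1.58 ± 0.41), TNFRSF1B (−1.85), CD38 (−1.80) and CD74 (−1.69) passed over a list alone. The Treg identity list had a median of −1.31 (11 of 21 over the list alone, adjusted p = 0.0782 with an estimated correlation). Its score was 5.13 ± 0.58 against 6.35 ± 0.66 (difference −1.22, exact permutation p = 0.00659, adjusted p = 0.0703), with −0.98 within the Pool series and −1.17 within a numbered series that held 1 such SOC library. FOXP3 had −1.96 ± 0.64 (adjusted p = 0.405 over all genes; 6.95 ± 1.20 against 8.86 ± 1.03), IL2RA −1.69 ± 0.52, CTLA4 −1.42 ± 0.51 and IKZF2 −1.31.

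All 30 proliferation genes were lower over the list alone in SOC Treg, with a median of −2.83, but the call was lost with an estimated correlation (adjusted p = 0.111). MKI67 had −3.35 ± 1.04 (3.16 ± 1.05 against 6.25 ± 1.84) and AURKA, a mitotic kinase, −3.79. The score was 3.47 ± 0.60 against 5.70 ± 1.68 (difference −2.24, exact permutation p = 0.0212, adjusted p = 0.113; Pool −1.73, the same 1 numbered library −2.35). Type I interferon genes, with IFI6 at −2.85 ± 0.67, had a median of −1.19 (7 of 33 lower over the list alone, adjusted p = 0.18 with an estimated correlation). For interferon gamma the median was −0.96 (7 of 23, adjusted p = 0.0981 with an estimated correlation). TP53INP1 had 1.66 ± 0.39, IL7R 0.78, CD40LG 0.84, IFNG −1.97 and IL2 1.65. Beside these, the erythroid list had a median of −3.84 (7 of 12 over the list alone, adjusted p = 0.194 with an estimated correlation), with HBB at −4.28 and ALAS2 at −4.83. The neutrophil list had −3.06 (adjusted p = 0.3 with an estimated correlation) and the monocyte and dendritic cell list −1.50 (0.26).

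Other lists past the preset correlation alone were tissue homing (−0.68), IL-2 and STAT5 (−0.58), immediate early (−0.35), glycolysis (−0.65), oxidative phosphorylation (−0.67), histones (−1.07), platelet (−0.03), conventional CD4 (0.84) and naive and central memory genes (0.37), with adjusted p of 0.111 to 0.581 with an estimated correlation. The naive and central memory list passed without the 4 small libraries (0.69, adjusted p = 0.0202 with an estimated correlation; score difference 1.06, exact permutation p = 0.0022, adjusted p = 0.0703). For the immediate early list the fitted median and the score difference (0.18) had opposite signs. Of the 32 lists, 18 passed with the preset correlation and 2 with an estimated one.

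Without the 4 small libraries edgeR called 0 genes (AK5 adjusted p = 0.102, NETO2 0.0963), as did RLE scaling, voom, the Pool series alone and the covariate fit, while DESeq2 called 11937 with them and 182 without. With the covariates the activation and inhibitory receptor lists lost their call (adjusted p = 0.308 and 0.0886 with an estimated correlation), and so did activation in the Pool series alone (0.0951) and both in the 2 numbered series alone. The count was 0 without any 1 of the 7 SOC libraries or without no-prophylaxis library 1, 5, 6, 7 or 11, 1 without library 9 or 10, and 4 without library 3 or 8.

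Whether SOC also differs from Orca-T with prophylaxis was examined in Tcon with 7 and 8 libraries. Lists fell together here while no gene passed over all 21205 with edgeR (2598 with an unadjusted p under 0.05, smallest adjusted p 0.112; DESeq2 919, voom 67). Inhibitory receptors had a median of −1.40 (5 of 12 lower over the list alone, adjusted p = 0.0303 with an estimated correlation) and a score difference of −0.85 (exact permutation p = 0.00482, adjusted p = 0.0514). HAVCR2 had the smallest p among them (−2.20 ± 0.47, adjusted p = 0.122; 3.06 ± 0.64 against 5.05 ± 0.87). Treg identity genes had a median of −1.23 (8 of 21, adjusted p = 0.0303 with an estimated correlation), with FOXP3 at −2.09 ± 0.58 (adjusted p = 0.134, 6 of 7 libraries) and CTLA4 at −1.58. Activation genes had −0.87 (4 of 16, adjusted p = 0.0304 with an estimated correlation), with CD74 at −1.97 ± 0.41 and TNFRSF1B at −1.71. Naive and central memory genes rose by a median of 1.06 (7 of 18, adjusted p = 0.0303 with an estimated correlation). TCF7 had 1.40 ± 0.34 (adjusted p = 0.129, 6 of 7), TXK 1.35, LRRN3 2.89, MAL 1.11 and SATB1 1.16.

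NFAT targets, the genes downstream of the calcineurin that tacrolimus blocks, were lower in SOC Tcon than in prophylaxis Tcon by a median of −0.58 (adjusted p = 0.0365 with an estimated correlation, 0 members past the threshold over the list alone). Their score was 1.22 ± 0.55 against 2.30 ± 0.51 (difference −1.08, exact permutation p = 0.00233, adjusted p = 0.0373, 7 of 7 libraries), with −0.74 within 1 numbered series. In prophylaxis against no prophylaxis the list was not lower: its median was 0.15 in Tcon (score 2.30 ± 0.51 against 1.89 ± 0.43, exact permutation p = 0.0842) and −0.02 in Treg (score difference 0.29, p = 0.241). Proliferation genes had a median of −2.62 (26 of 30 lower over the list alone, adjusted p = 0.131 with an estimated correlation), MKI67 −2.85 ± 0.75 (adjusted p = 0.129). In the same comparison the monocyte and dendritic cell score was 2.50 ± 2.92 against 6.68 ± 1.09 (difference −4.18, exact permutation p = 0.000777, adjusted p = 0.0249, 7 of 7). It was −2.56 within the Pool series and −2.99 within 1 numbered series. The other held 2 SOC and no prophylaxis Tcon, and the permutation did not keep to series, so a part of the −4.18 can come from series. Of its 17 members 16 were lower over the list alone (median −2.75, adjusted p = 0.0805 with an estimated correlation), and CD68 had −3.32 and CST3 −3.12. Both interferon lists had medians nearer 0 (type I −0.28, gamma −0.40).

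Of the 32 lists, 18 passed with the preset correlation and 5 with an estimated one. All 5 lost that call with the monocyte and erythroid covariates (adjusted p from 0.0667 for Treg identity to 0.379 for activation, with an estimated correlation). The 2 numbered series alone left none, and the Pool series alone left 4 (naive and central memory 0.0779). With 1 library left out the count was 11 without SOC library 2, 1 without SOC library 6 and 1 without prophylaxis library 4.

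The same question in Treg (4 SOC and 8 prophylaxis libraries of usable depth) left no list past the threshold with an estimated correlation. Monocyte and dendritic cell genes had a median of −2.32 in SOC (10 of 17 lower over the list alone, adjusted p = 0.105 with an estimated correlation). Their score was 3.21 ± 1.84 against 5.51 ± 0.91 (difference −2.30, exact permutation p = 0.0101, adjusted p = 0.194), and LYZ was 5.95 ± 2.62 against 8.96 ± 1.31. Neutrophil and myeloid precursor genes had −4.54 (9 of 14, adjusted p = 0.146 with an estimated correlation), with the granule genes MPO at −5.20 ± 1.48, ELANE −8.97 and AZU1 −5.75, the last 2 each held on 2 lines of the table. Without the 4 small libraries both lists passed (adjusted p = 0.041 with an estimated correlation). Treg identity (−1.06, 0.146), inhibitory receptors (−1.06, 0.105), activation (−0.68, 0.105), immediate early (−0.64, 0.105), erythroid (−3.11, 0.146), proliferation (−1.98, 0.249), oxidative phosphorylation (−0.81, 0.183) and ribosomal protein genes (−0.81, 0.31) passed with the preset correlation alone, the second value being the adjusted p with an estimated correlation. For ribosomal proteins the score difference (0.19) had the opposite sign. Past the threshold over a list alone were also THEMIS (2.14 ± 0.58, 3 of 4), LRRN3 (3.24 ± 0.90), EGR1 (−3.50), CLEC7A (−2.36), CCL3 (−4.15) and CCL4 (−3.69), the last 2 held on 3 lines each. FOXP3 had −1.46 ± 0.65, MKI67 −2.34 ± 1.03 and CTLA4 −0.99. No gene passed over all 22962 with edgeR (989 with an unadjusted p under 0.05; DESeq2 9467, 43 without the small libraries; voom 0). With the preset correlation 22 lists passed, and 0 with an estimated one.

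What the single agent adds to Orca-T was asked in Tcon with 8 prophylaxis and 10 no-prophylaxis libraries. No gene passed with edgeR (461 with an unadjusted p under 0.05; DESeq2 2, voom 0). Immediate early genes had a median of 0.66, 17 of 18 higher (adjusted p = 0.23 with an estimated correlation). Their score differed by 0.81 (exact permutation p = 0.0136, adjusted p = 0.218, 7 of 8 libraries), by 1.13 within the Pool series and by 0.11 within 1 numbered series. NF-kB targets had a median of 0.51 (adjusted p = 0.304 with an estimated correlation) and a score difference of 0.70 (exact permutation p = 0.012, adjusted p = 0.218). Past the threshold over a list alone were CD83 (1.80 ± 0.51, 7 of 8), OSM (1.43 ± 0.43, 6 of 8) and SGK1 (1.88 ± 0.57, 6 of 8), a kinase induced by glucocorticoids. In the same libraries the monocyte and dendritic cell score was 6.68 ± 1.09 against 5.44 ± 1.96 (exact permutation p = 0.135, 4 of 8 libraries; fitted median of the list 0.24) and LYZ 9.74 ± 1.30 against 8.43 ± 2.44, so a part of monocytes in these differences is open. With the preset correlation 11 lists passed, and 0 with an estimated one. Further ones were glucocorticoid response (0.36), ribosomal protein (0.36), neutrophil (0.76), p53 (0.22), type I interferon (−0.75), interferon gamma (−0.45), Th1 (−0.64), proliferation (−0.53) and CD8 and γδ genes (−0.75), where adjusted p was at least 0.23 with an estimated correlation. FOXP3 (−0.17 ± 0.47), IL2RA (−0.31), CTLA4 (0.09), MKI67 (−0.71), IL7R (−0.06), IFNG (0.07) and IL2 (−1.02) did not pass.

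In Treg (8 prophylaxis and 11 no-prophylaxis libraries of usable depth) the same comparison also called 0 genes with edgeR (579 with an unadjusted p under 0.05; DESeq2 1, voom 0). CISH, a STAT5 target that restrains cytokine signalling, had −1.83 ± 0.49 (4.56 ± 1.05 against 6.36 ± 1.14, 8 of 8 libraries). IFI6 had −1.86 ± 0.50 (5 of 8) and MPO 2.98 ± 0.93 (7 of 8), and these 3 passed over their list alone. Type I interferon genes had a median of −0.94 (adjusted p = 0.236 with an estimated correlation). Their score differed by −0.98 (exact permutation p = 0.0365, adjusted p = 0.416, 7 of 8), and by −0.71, −1.71 and −1.16 within the 3 series. Proliferation genes had −0.74 (0.422), with a score difference of −1.14, −4.13 and 0.59 within the series, so the direction did not hold in every series. The −1.71 and the −4.13 rest on 1 prophylaxis library, the one labelled Treg with a FOXP3 of 2.80. In all, 17 lists passed with the preset correlation and 0 with an estimated one. By median and adjusted p with an estimated correlation, these included Th1 (−0.64, 0.236), interferon gamma (−0.53, 0.343), Treg identity (−0.34, 0.422), inhibitory receptor (−0.41), activation (−0.33), IL-2 and STAT5 (−0.44), ribosomal protein (0.87, 0.51), monocyte (0.46) and neutrophil genes (0.93). FOXP3 had −0.50 ± 0.55, IL2RA −0.78, CTLA4 −0.43, IKZF2 −0.50 and MKI67 −1.01 ± 0.76. The 2 numbered series alone called 22 genes.

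Whether an arm acted differently in Treg and in Tcon was tested as the difference of the 2 arm effects. For SOC against no prophylaxis it was 0.42 ± 1.12 for MKI67, 0.26 ± 0.81 for FOXP3, 0.02 ± 0.63 for CTLA4 and −0.79 ± 0.69 for IL2RA. For prophylaxis against no prophylaxis it was 0.09 ± 0.97 for MKI67 and −0.06 ± 0.73 for FOXP3. No gene passed in either with edgeR (136 and 177 with an unadjusted p under 0.05, smallest adjusted p 1; DESeq2 12439 and 3, and 2 and 5 without the small libraries; voom 0). The smallest p belonged to LEFTY1 (6.47), BFSP1 (2.02), GPR179 (5.94), HOXA4 (−5.82) and SLC4A3 (6.24) for SOC, and to B3GALT4 (6.94, on 5 lines of the table), DEFA1 (−8.65, on 2 lines), WFIKKN2 (4.64), INE2 (5.82) and OSM (−1.60 ± 0.57) for prophylaxis. With the preset correlation 18 lists passed for SOC and 8 for prophylaxis, and 0 with an estimated one. For SOC they included Th1 (0.65), naive and central memory (−0.43), ribosomal protein (−0.61), erythroid (−3.29) and monocyte genes (0.53; adjusted p of at least 0.423 with an estimated correlation). Of the 226 genes called in SOC Tcon, 224 were tested in Treg and all 224 had the same direction there, with median folds of −1.82 for the lower and 1.20 for the higher genes. Among the 20576 genes tested in both cell types 74.1% had the same direction. The 2 cell types can come from the same people, so the signs are not independent.

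**Figure D4:**
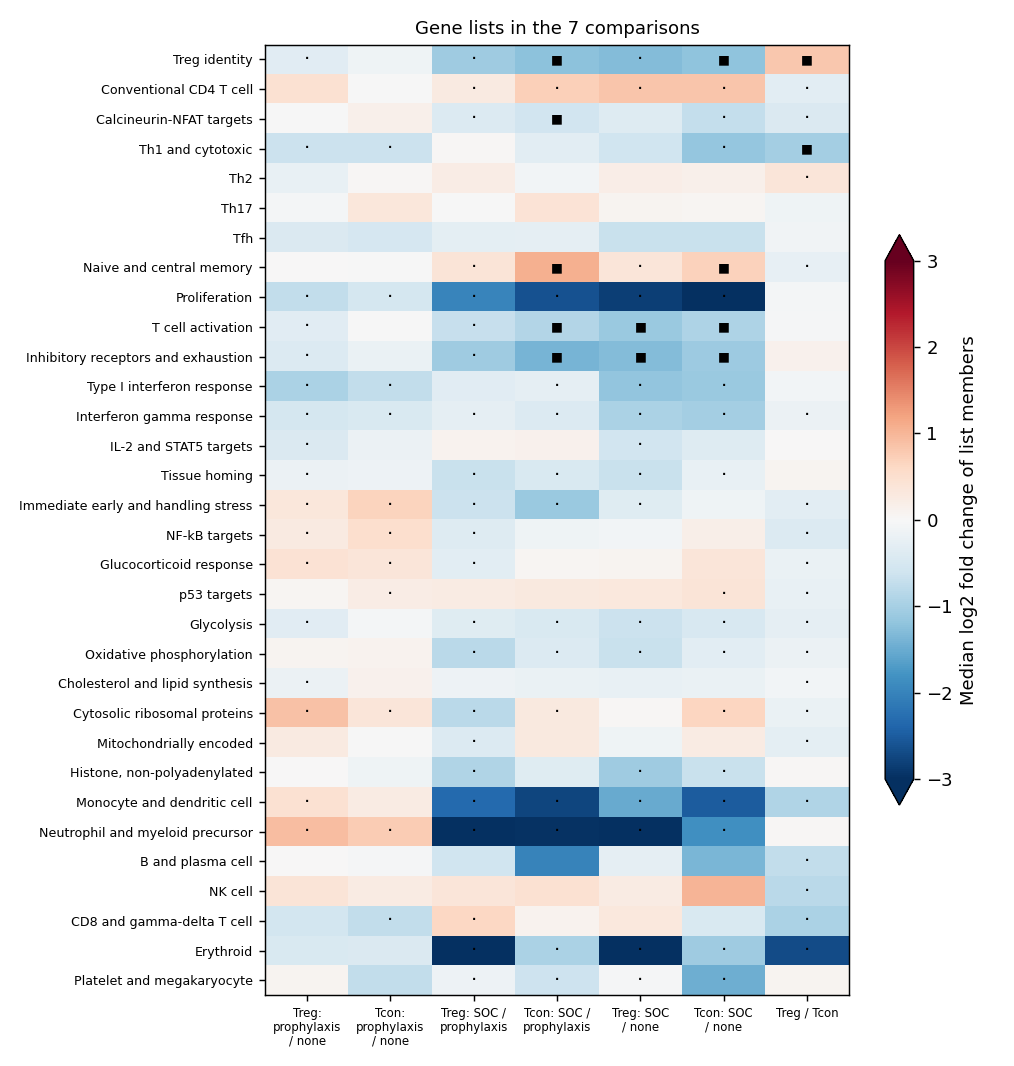
Median log2 fold change of the members of 32 lists (lines of the heatmap) in 7 comparisons (columns), with colour clipped at 3 in either direction. Filled squares mark lists past the threshold with an estimated correlation and dots those past it with the preset correlation alone; proliferation in Tcon of SOC against no prophylaxis was −3.02.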

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

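The tests of the proliferation pattern, of the 2 libraries with discordant FOXP3 and of depth, and the splits of SOC and of prophylaxis against no prophylaxis in Treg and of SOC against no prophylaxis in Tcon, were chosen after the results were seen; the other splits and the test of exonic length were fixed before. Values far from the rest of their group were sought in 110 groups of values, and 17 stood apart. By chance about 1 in 20 groups would, if the values had a normal spread. No-prophylaxis Treg, the largest group with 11 libraries, was not checked.

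Proliferation transcripts were lower in Tcon of SOC than of no prophylaxis, with a median log2 fold change of −3.02 and a median SE of 0.75. With the monocyte and erythroid scores as covariates the median was −2.58 and the SE 0.97. Over all 226 called genes the median size of the fold went from 1.87 to 1.51 (smaller in 196). Their SE went from 0.42 to 0.50 (larger in 218), and no call was left. By the rule used, RNA of monocytes and erythroid cells is argued against as the whole cause. That rule took the SE of single genes, which vary together, and scores can miss a part of such RNA. It stays open as a part, whose size this test cannot settle. Without the libraries with over 35000 genes the median was −3.21, and the smallest of the within-series differences of the score was −2.24, which argues against background reads and library series. A difference in T cell division between the arms stays open as a hypothesis. It was found and tested on the same libraries, and patients were not given in the labels, so other differences between the arms' patients also stay open.

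The library labelled prophylaxis Treg 1 had a FOXP3 of 2.80 log2 CPM (others of its group 7.09 to 9.72) and an IKZF2 of −2.40 (4.46 to 6.24), and the library labelled SOC Tcon 2 a CTLA4 of 8.00 (4.26 to 5.71) and an IFNG of −3.98 (0.14 to 2.78), each far from its group. Its FOXP3 of 8.73 was the highest of SOC Tcon (others 3.31 to 6.14) but not of all Tcon (highest 9.09). The Treg identity score without FOXP3 was 6.25 in the library labelled Tcon, where 22 other Treg had a median of 5.96. Other Tcon had a median of 5.07 and a maximum of 6.73. In the library labelled Treg the score was 3.44, below all 24 other Tcon (lowest 3.65). An exchange of labels would give this, and the 2 belong to different arms of the same series. In that series no-prophylaxis Tcon 1 and 2 had FOXP3 of 9.09 and 9.07. Their Treg identity scores with FOXP3 were 6.84 and 6.29, against 6.37 in SOC Tcon 2, so these values do not single it out. SOC Treg 2, of the library number before it, held 3888 counts, so an exchange within the arm could not be checked. Activated conventional T cells in the library labelled SOC Tcon 2 cannot be told apart from an exchange of labels. The IKZF2 of that library, 4.60, lies between the medians of other Tcon (3.78, maximum 5.84) and other Treg (5.02).

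Counts in over 35000 genes were present in 15 libraries, all of the Pool series, against 19273 to 29653 genes in the other 33 of at least 1000000 counts. Greater depth is argued against, as these libraries had a median of 28.5 M counts (M, 1000000) and the 13 other Pool libraries 59.3 M. Over 11849 genes silent in the other libraries, the summed count rose with exonic length (Spearman 0.662, genes are not independent). Reads from genomic DNA or other unprocessed sequence would give this. Counts of RNA fragments can rise with length as well, so the value cannot tell these sources apart. Olfactory receptors, silent in T cells, had a count for a median of 296 of 381 genes in these and 23 in the others. All arms and both cell types held such libraries, 2 or 3 in each of the 6 groups, but the groups differ in size. Among Treg of usable depth they were 2 of 4 SOC, 3 of 8 prophylaxis and 2 of 11 no-prophylaxis libraries. In Tcon they were 2 of 7, 3 of 8 and 3 of 10. No biological explanation was tested.

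The Tcon libraries of SOC and no prophylaxis were split 100 times, the real split included. Only the real one gave as many as 226 genes (1 of 100, highest other 103). That is the smallest share 100 splits can give, in 1 of 9 comparisons, and the splits did not keep to series. Chance is thus made less likely for this count but not excluded. For the 2 genes of SOC against no prophylaxis in Treg, 6 of 100 splits gave as many (highest other 3031), and chance could not be excluded. For counts of 0 every split is as large: 100 of 100 for prophylaxis against no prophylaxis in Treg (highest other 3135) and Tcon (641), 100 of 100 for SOC against prophylaxis in Treg (3) and Tcon (0), 40 of 40 for Treg against Tcon (1328), and 40 of 40 for the difference of arm effects under SOC (0) and under prophylaxis (4787). Splits with 3031, 3135, 1328 and 4787 calls, where the real ones gave 2 or 0, point to a structure of the libraries whose cause was not tested, and only 2, 3, 2 and 2 of these splits called 10 or more genes.

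The other values that stood apart were totals of 59.4 M in SOC Tcon 5 (others 20.1 to 34.9) and 95.5 M in prophylaxis Treg 8 (0.782 to 36.1). Hemoglobin made up 7.61% of no-prophylaxis Tcon 4 (others up to 2.46%) and 17.5% of prophylaxis Tcon 7 (up to 2.05%). Mitochondrial transcripts made up 3.36% of SOC Treg 5 (1.61% to 1.73%), 4.47% of SOC Tcon 5 (1.40% to 2.26%) and 4.94% of no-prophylaxis Tcon 1 (0.701% to 2.61%), and ribosomal protein transcripts 15.4% of prophylaxis Treg 5 (2.45% to 8.23%) and 10.4% of prophylaxis Tcon 8 (2.27% to 4.78%). MKI67 was 1.19 in SOC Tcon 4 (3.00 to 3.77) and IL2 −3.25 in prophylaxis Tcon 2 (−1.78 to −0.46). In no-prophylaxis Tcon the neutrophil score was 6.38 in library 6 (−0.39 to 3.20) and the platelet score 5.68 in library 8 (0.00 to 2.88).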

How the results depend on the processing

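Fits without the 2 libraries with discordant FOXP3 (low in a library labelled prophylaxis Treg, high for its group in one labelled SOC Tcon), without those with over 35000 genes, with lines of one symbol summed, with monocyte and erythroid covariates, with pairs of library numbers, and DESeq2 without the small libraries were chosen after seeing the data; the others were planned. Of the alternative values of the counts of genes past the threshold, 106 kept within 1.5 times the count reported and 50 moved. Named genes kept direction and side of the threshold in 5256 alternatives, became weaker in 276, stronger in 275 and reversed in 2; lists kept both in 1770, became weaker in 697 and reversed in 28. Where no other reason is given, the cause was not tested. With fry, 6 lists passed for Treg SOC vs no prophylaxis and 9 for Tcon SOC vs no prophylaxis. It gave 7 for Tcon SOC vs single-agent prophylaxis and 0 elsewhere. Depth left 4 usable SOC Treg libraries. Simulated genes at a log2 fold change of 2 were recovered in 46% in Treg of SOC against no prophylaxis. The share was 32% without the small libraries and 66% in Tcon. Each run planted its own genes, simulated as independent and without series effects.

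For Treg SOC vs no prophylaxis (2 reported), DESeq2 called 11937 and, without the small libraries, 182. RLE scaling, the Pool series alone, no libraries under 1000000 counts, voom, all 52 in one fit, no discordant or small libraries, no libraries over 35000 genes, and the covariates each left 0. The 2 numbered series alone, 2 surrogate variables and no discordant libraries each left 1. RLE scaling moved the median log2 fold change of all genes from −0.06 to 0.43 here, from 0.07 to 0.38 for Treg single-agent prophylaxis vs no prophylaxis, from −0.18 to 0.03 for Treg SOC vs single-agent prophylaxis, and from 0.05 to 0.70 for the difference of arm effects under prophylaxis. For Treg single-agent prophylaxis vs no prophylaxis (0 reported), DESeq2 called 1, the 2 numbered series alone 22, and DESeq2 without the small libraries 2. For Treg SOC vs single-agent prophylaxis (0), these called 9467, 1 and 43. For Tcon SOC vs no prophylaxis (226), DESeq2 called 1478 with and without the small libraries, no filter 7, the Pool series alone 0, the numbered series alone 0, voom 1303, no discordant libraries 71, no discordant or small libraries 71, no libraries over 35000 genes 478, and the covariates 0. The 1-series fits had fewer libraries, and no filter tested more genes. For Tcon single-agent prophylaxis vs no prophylaxis (0), DESeq2 called 2 with and without the small libraries. For Tcon SOC vs single-agent prophylaxis (0), DESeq2 called 919 with and without them, voom 67, 2 surrogate variables 1, all 52 in one fit 35, no discordant libraries 11, and neither discordant nor small libraries 11. For Treg vs Tcon (0), DESeq2 called 10811, voom 7, no discordant libraries 29, neither discordant nor small libraries 12, no libraries over 35000 genes 1, and DESeq2 without the small libraries 60. For cell type by arm, SOC vs no prophylaxis (0), DESeq2 called 12439, and 2 without the small libraries. For cell type by arm, single-agent prophylaxis vs no prophylaxis (0), DESeq2 called 3, and 5 without them. Of the 11937 and 9467 DESeq2 calls in Treg, 11897 and 9451 were higher in SOC, the group with 3 near-empty libraries, and 182 and 43 calls were left without the small libraries. Leaving out 1 library gave 0 to 4 genes for Treg SOC vs no prophylaxis, 0 to 651 for Tcon SOC vs no prophylaxis, 0 to 11 for Tcon SOC vs single-agent prophylaxis, and 0 to 0 elsewhere.

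The labels name no patient, so no pairing belongs to the design. The numbers in the library names put 25 Treg beside a Tcon of the same arm (the next number, or in the Pool series the number 16 places on where there is one), and both libraries of 21 pairs had at least 1000000 counts. Deviations from the group and series means correlated by over 0.1 in 18 of the 21 pairs (−0.185 to 0.802, median 0.406; other pairs of the same arm and series −0.164), and 15 of 21 Tcon and 15 of 21 Treg correlated best with their own partner. This is a hint from the data, not the design, and a cause other than a shared patient was not tested. For Treg vs Tcon (0 reported), the pairs as a block gave 245 genes (134 higher, 111 lower in Treg), and the same libraries without the block 10. FOXP3 passed in both (1.66, adjusted p = 0.00118, and 1.64, 0.0178), so its call came with the choice of libraries. Treg identity with an estimated correlation had adjusted p = 8.12e-05 and 5.91e-07. Neither library with discordant FOXP3 is in these pairs, so the values cannot be told apart from the effect of leaving those libraries out. The differences of arm effects kept 0 genes in both fits. In cell type by arm, SOC vs no prophylaxis, NFAT targets with an estimated correlation had adjusted p = 0.00546 with the block and 0.0225 without it. Lists that reversed there under camera were, with the block, type I interferon (0.0428), immediate early (4.96e-07), NF-kB (0.000529), glucocorticoid (1.44e-07), glycolysis (0.0351), oxidative phosphorylation (0.0104), ribosomal (0.0169) and mitochondrially encoded genes (0.0351). Without the block they were immediate early (0.00132), NF-kB (0.0156), glucocorticoid (0.00136) and mitochondrially encoded genes (0.0385).

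Reversed with DESeq2 were CXCL10 in Treg SOC vs no prophylaxis (adjusted p = 0.0184) and CLEC10A in Treg SOC vs single-agent prophylaxis (adjusted p = 0.00408). The other lists that reversed under camera did so with adjusted p as follows. With the covariates, in Treg SOC vs no prophylaxis, these were immediate early (5.89e-05) and platelet (3.13e-08). In Treg SOC vs single-agent prophylaxis they were proliferation (0.0158), interferon gamma (0.000299), immediate early (0.00462), glucocorticoid (0.0285), glycolysis (3.36e-05), mitochondrially encoded (3.02e-05) and platelet (1.19e-20). In Tcon they were neutrophil for SOC vs no prophylaxis (0.016) and platelet for SOC vs single-agent prophylaxis (0.019). In the Pool series alone these were mitochondrially encoded genes in Treg SOC vs single-agent prophylaxis (0.00297), erythroid genes in Tcon SOC vs no prophylaxis (0.00336), glycolysis in cell type by arm, SOC vs no prophylaxis (0.00879), and mitochondrially encoded genes in cell type by arm, single-agent prophylaxis vs no prophylaxis (1.46e-05). In the 2 numbered series alone ribosomal proteins reversed in Tcon single-agent prophylaxis vs no prophylaxis (0.000199).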

Other observations

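LYZ and HBB, abundant in monocytes and in red cells, were read in every Tcon group. LYZ was 6.06 ± 2.48 log2 CPM in SOC (n = 7), 9.74 ± 1.30 in prophylaxis (n = 8) and 8.43 ± 2.44 in no prophylaxis (n = 10), and HBB averaged 8.81, 11.84 and 11.11.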
